A study of Rattus norvegicus with 6 samples.

How the data were processed

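RNA from rat C6 glioma cells was measured in 6 libraries, 3 from untreated cells and 3 from cells given 15 μM Thiotert for 24 h, and each library was placed in its group by its treatment label. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with the NEBNext Ultra RNA kit. No label speaks of strand, so reads from overlapping or antisense genes cannot be told apart, and genes that share reads with near-identical copies are uncertain.

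The authors deposited a table of raw counts per gene and a table of FPKM values, each with gene lengths, symbols, coordinates and biotypes. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, and they name GRCh38. GRCh38 is a human build, while the identifiers in the deposited table are rat Ensembl identifiers, so the build behind the coordinates is not given in the sources used here, and coordinates are printed as deposited. In the deposited FPKM table each value equals the count times a constant over the gene length, with 1 effective library size per library, 0.915 to 0.924 of the total count in control and 1.09 to 1.11 in treated libraries. Divided by TMM factors taken over all genes, these values gave 0.999 to 1.01. The deposited counts therefore carry all the information in the FPKM table, and FPKM values were used only in alternatives. Gene symbols came from the deposited tables themselves.

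Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr at a minimum count of 10, which left 13556 of 31142. Library sizes were scaled by TMM, dispersions were fitted with the robust quasi-likelihood method (common biological coefficient of variation 0.085), and treated and control libraries were compared with the quasi-likelihood F test without covariates. P-values were adjusted by the Benjamini-Hochberg method over the 13556 genes and called at 0.05. The SE of a log2 change was taken as its size divided by the square root of F. Levels are means ± SD of TMM-normalised CPM, the count scaled to library size, over 3 libraries. At 14159479 to 15757281 counts per library, 10 counts in a library correspond to less than 1 CPM, and calls for genes near that level rest on few counts. Shares of counts were compared with an exact two-sided permutation test, whose smallest p with 3 libraries against 3 is 0.1.

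Before the data were examined, 30 gene lists were written: 22 main lists, 5 lists of cell type markers and 3 lists on RNA quality. Lists with at least 5 tested entries (29) were tested with camera from limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Estimated correlations and the rotation test fry were alternatives. Genes to be named were fixed by a rule set at the same time: 7 genes named in advance, the 5 largest rises and 5 largest falls among called genes with a symbol, a log2 CPM of at least 3 and non-overlapping groups, up to 3 called members of each main list in its majority direction and 1 in the other, and the most abundant members, at most 2, of each marker and quality list. Some list symbols had no row in use under that symbol, and such genes were not analysed here. Some genes that the rule names are not reported here.

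The alternatives chosen in advance were RLE size factors, library totals alone and upper-quartile factors, no low-count filter, a minimum count of 50, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, protein-coding genes alone, and each library left out in turn. A correction for transcript length and genomic span (a loess offset per library) and the removal of list entries with a shared symbol were added after seeing the data. Columns of other series were 0.

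The scripts were tested on simulated counts drawn for the 13556 genes from the means and sizes of these libraries, with 200 genes changed. For the comparison of Thiotert with control, edgeR recovered 77% of the simulated 2-fold and 58% of the 1.5-fold changes, with 14 of 149 calls false. Of 2 simulated lists that changed both were called, and 0 of 20 unchanged lists were called, by camera with preset or estimated correlations. Genes were drawn independently of each other, and few were changed. The simulation therefore does not test camera on lists of correlated genes, or the scaling where most genes change.

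Replicates were compared before averaging. The chi-square per degree of freedom between libraries was 3.40 to 4.97 among controls, 2.64 between Thiotert replicates 1 and 3, 29.3 and 30.2 between these and Thiotert replicate 2, and 126 to 162 between groups. Every pair differed by more than counting noise, so no library was treated as a copy of another; this does not show that the libraries come from separate cultures.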

Results

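RNA sequencing was carried out on C6 cells, a rat glioma line that grows in culture and carries features of glial cells. The labels describe 3 untreated control libraries and 3 libraries from cells given 15 μM Thiotert for 24 h. Thiotert is known as an inhibitor of thioredoxin reductase, the enzyme that keeps thioredoxin in its reduced, working form. The series title asks how Thiotert acts in these cells, and the design implies 1 comparison, treated against control. Total counts per library lay between 14159479 and 15757281, and the mean total of the treated libraries was 1.01 times that of the controls. Of 31142 genes in the table, 13556 held enough counts to be tested. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

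After 24 h with Thiotert, transcripts for mitosis (32 of 32 genes), DNA replication (30 of 31), sterol synthesis (21 of 23) and glycolysis and hypoxia (21 of 29) fell, and targets of the stress transcription factor ATF4 (20 of 31) rose. These lists were called by camera, a test of a gene list against the other genes, with preset and with estimated correlations. *Top2a*, which encodes the topoisomerase that untangles DNA before cell division, fell from 740 ± 20.9 to 46.7 ± 1.12 CPM (count scaled to library size; SD, n = 3 per group), 15.8-fold lower. *Trib3*, a pseudokinase gene induced in the integrated stress response, rose from 41.1 ± 0.888 to 272 ± 5.53 CPM, a 6.62-fold change. *Ddit3*, which encodes the stress-induced transcription factor CHOP, rose 5.81-fold, from 62.5 ± 1.87 to 363 ± 49.2 CPM. CPM values are TMM-normalised throughout, and a log2 change is Thiotert minus control with its standard error (SE).

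By edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, 9373 of the 13556 genes changed (69.1%), of which 4730 were higher and 4643 lower with Thiotert. A change of at least 2-fold was found in 2859 of these, with 1418 higher and 1441 lower. The 3 treated and the 3 control values did not overlap in 9846 genes (72.6%), where chance gives 10%. The balance of directions rests on the scaling. TMM put 50.5% of the called genes higher, upper-quartile factors put 61.5% higher, and library totals alone put 66.2% higher (6502 higher and 3314 lower), since these 2 scalings moved the median log2 change of all genes by 0.16 and 0.24. Changes below are given relative to the TMM scale, and the medians of the 12 lists called below kept their sign under all 4 scalings. The first principal component, with 82.8% of the variance, separated the groups, and the second, with 5.21%, set Thiotert replicate 2 farthest from its group. Without that library 9566 genes were called.

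Of the 7 genes chosen in advance, 3 fell and 4 rose. *Txnrd1*, which encodes the cytosolic thioredoxin reductase (chromosome 7, 20830045 to 20907863 in the deposited coordinates, whose build the file does not name), fell from 184 ± 6.84 to 141 ± 7.93 CPM, a log2 change of -0.39 with an SE of 0.060 (edgeR adjusted p = 3.4e-05). *Txn1*, the gene of its substrate thioredoxin, fell from 381 ± 10.4 to 231 ± 13.1 CPM, with a log2 change of -0.73 (SE 0.058; edgeR adjusted p = 1.9e-08). *Hmox1*, which encodes the heme-degrading enzyme heme oxygenase 1 (chromosome 19, 13467244 to 13474079), rose 3.64-fold from 41.7 ± 2.53 to 152 ± 1.99 CPM (SE of the log2 change 0.066; edgeR adjusted p = 1.3e-12). *Gclm*, the modifier subunit of the first enzyme of glutathione synthesis, fell from 57.4 ± 0.973 to 43.3 ± 2.76 CPM, and that call was lost with library totals alone. *Gadd45a*, a growth-arrest gene, rose 2.04-fold from 103 ± 4.85 to 210 ± 10.1 CPM, and *Cdkn1a*, which encodes the cell-cycle inhibitor p21, rose 1.36-fold from 165 ± 13.3 to 226 ± 2.21 CPM.

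**Figure D1:**
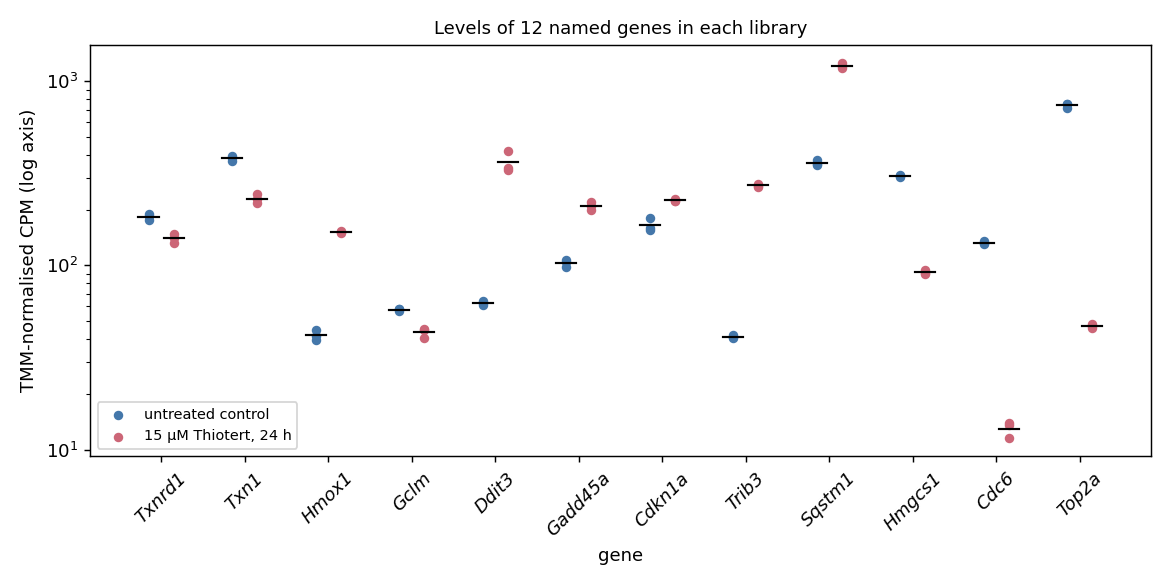
Levels of 12 genes in each library in TMM-normalised CPM on a log axis, with 3 untreated control libraries in blue, 3 Thiotert libraries in red and a bar at each group mean. *Hmox1*, *Ddit3*, *Gadd45a*, *Cdkn1a*, *Trib3* and *Sqstm1* were higher in every treated library than in any control, from 41.1 to 272 CPM for *Trib3*, and the other 6 were lower in every treated library, from 740 to 46.7 CPM for *Top2a*.

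Targets of NRF2, the transcription factor of the antioxidant response, moved both ways. Of 28 tested entries 11 rose, 12 fell and 5 did not pass. The members that rose included *Hmox1* and *Sqstm1* (log2 change 1.76), which encodes the autophagy receptor p62. An entry named *Ftl1* (2.17) rose too, but lay at only 1.65 and 7.43 CPM, shares its symbol with another row and is uncertain. That other, far more abundant *Ftl1* row rose from 1531 to 4235 CPM (1.47, edgeR adjusted p = 1.9e-07). The members that fell included *Me1* (-1.13), *Gclc* (-1.09), which encodes the catalytic subunit of the same glutathione-synthesis enzyme, and *Abcc1* (-0.82). The list was not called by camera (adjusted p = 0.92); its median log2 change was -0.06, its mean 0.17, and camera's direction was up, or down without the 3 entries that share a symbol. The thioredoxin, glutathione and peroxide-removing enzymes, 6 of whose 29 entries also stand in another list, also moved both ways, with 10 higher and 12 lower (camera adjusted p = 0.92). In this list the endoplasmic reticulum peroxidase genes *Gpx7* (-2.83, from 5.07 to 0.711 CPM) and *Gpx8* (-0.77) fell, and *Gpx1* (1.85), the gene of the main cytosolic glutathione peroxidase, rose. The treated level of *Gpx7* rests on few counts. The mitochondrial counterparts of the 2 thioredoxin-system genes given above, named after their values were seen, rose: *Txn2* from 164 to 221 CPM (0.43) and *Txnrd2* from 17.2 to 24.6 CPM (0.51). The medians of both lists turned positive with library totals alone and with upper-quartile factors, so no direction is given for either.

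The cell-cycle lists showed the largest median changes. All 32 mitosis and G2/M genes fell, with a median log2 change of -2.32, 4.99-fold lower (camera adjusted p = 4.8e-19). *Anln*, a scaffold of the dividing cell's contractile ring, fell from 555 to 47.1 CPM (log2 change -3.56), and *Espl1*, the gene of the protease separase, from 208 to 24.7 CPM (-3.07). Of 31 DNA replication and S phase genes, 30 fell and 1 did not pass, with a median of -1.85 (camera adjusted p = 1.1e-15). Among them, *Cdc6* (-3.36) and *Cdc45* (-3.03) act in starting replication and *Pole* (-2.96) encodes a replicative polymerase subunit. In the list of homologous recombination and the Fanconi pathway 26 of 30 genes fell and 4 rose, with a median of -1.33 (camera adjusted p = 2.9e-07). *Fanci* (-2.90) and *Fancd2* (-2.64) fell, and *Fance* (0.94) rose. With a correlation estimated from each list, the adjusted p of these lists was 0.049, 0.037 and 0.037.

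Of 24 tested p53 targets 15 rose and 5 fell, with a median log2 change of 0.42 (camera adjusted p = 0.012, but adjusted p = 0.17 with an estimated correlation). *Bbc3*, which encodes the pro-apoptotic protein PUMA, rose from 11.98 to 53.1 CPM (2.15), *Tp53inp1* (1.35) and the antiproliferative gene *Btg2* (1.25) rose, and *Polk* (-0.68), a translesion polymerase gene, fell. Pro-apoptotic genes divided into 8 higher, 5 lower and 10 that did not pass (camera adjusted p = 0.63). *Bax* (0.84) and *Bid* (0.69) rose and *Casp8* (-0.87) fell. Of 11 anti-apoptotic genes 3 rose and 7 fell (camera adjusted p = 0.37), among them *Birc5* (-1.66), also a mitotic gene and in the mitosis list, and *Cflar* (-0.90), an inhibitor of caspase-8.

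The targets of ATF4, the transcription factor of the integrated stress response, rose in 20 of 31 tested genes and fell in 1, with a median log2 change of 0.62 (camera adjusted p = 7.7e-07; adjusted p = 0.049 with an estimated correlation). Besides *Trib3* (2.73) and *Ddit3* (2.54), *Slc3a2*, the heavy chain of amino acid transporters, rose from 361 to 1344 CPM (1.90). *Psat1* (-0.36), an enzyme gene of serine synthesis, was the gene that fell, and lost its call with library totals alone. Chaperones of the endoplasmic reticulum and genes of the unfolded protein response went the other way, with 16 of 28 lower and 6 higher and a median of -0.35 (camera adjusted p = 0.013; adjusted p = 0.13 with an estimated correlation). *Pdia6*, a disulfide isomerase gene, fell from 1238 to 434 CPM (-1.51), and *Edem1* (-1.36) and *Creld2* (-1.19) fell as well. *Manf*, at 0.473 and 1.26 CPM, passed the main test (edgeR adjusted p = 0.034), but its groups overlapped and the call was lost in 9 alternatives. Cytosolic heat shock genes were not called (3 higher, 6 lower, 9 not passing; camera adjusted p = 0.37), with *Hsp90aa1* (-0.89) and *Hspa4l* (-1.34) lower and the co-chaperone gene *Bag3* (0.79) higher; that list was called under a length correction (camera adjusted p = 0.038).

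Autophagy and lysosome genes rose in 25 of 34 cases and fell in 3, with a median log2 change of 0.35 (camera adjusted p = 8.4e-06; adjusted p = 0.075 with an estimated correlation). *Sqstm1* rose from 360 to 1216 CPM, *Gabarapl1* (2.47), which encodes an ATG8-family protein of the autophagosome, from 22.6 to 125 CPM, and *Atg14* (1.39) from 9.16 to 23.9 CPM, while the mitophagy receptor gene *Bnip3* (-0.44) fell. The 31 proteasome subunits were split, with 11 higher and 8 lower (camera adjusted p = 0.65); *Psmd8* (0.65) rose and *Psmd1* (-0.77) fell.

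Sterol synthesis genes, targets of SREBP2, fell in 21 of 23 cases and none rose, with a median of -1.18 (camera adjusted p = 3.8e-09; adjusted p = 0.037 with an estimated correlation). *Acat2* (-1.91) fell from 372 to 99.0 CPM and *Hmgcs1* (-1.73), an early enzyme of the pathway, from 305 to 92.1 CPM. Glycolysis and hypoxia genes fell in 21 of 29 cases and rose in 4, with a median of -0.67 (camera adjusted p = 7.2e-05; adjusted p = 0.049 with an estimated correlation). *Ldha*, which encodes a lactate dehydrogenase subunit, fell from 2644 ± 174 to 621 ± 8.08 CPM (-2.09), and *Pfkl* (-1.68) and *Pdk1* (-1.61) fell too; an entry named *Aldoa* (2.78), at 0.494 and 3.40 CPM, is 1 of 2 with that symbol and is uncertain. Nuclear genes of the respiratory chain were divided, with 8 higher and 9 lower of 29 (camera adjusted p = 0.63), such as *Ndufa1* (1.53) and *Ndufs1* (-0.87). *Cox6c* (-0.56) was called, but not under 5 alternatives.

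Extracellular matrix genes and targets of TGF-beta and YAP fell in 23 of 29 cases and rose in 1, with a median of -1.06 (camera adjusted p = 3.4e-07, but adjusted p = 0.30 with an estimated correlation). *Tnc*, the gene of tenascin-C, fell from 2507 ± 109 to 514 ± 17.4 CPM (-2.29), and *Col5a1* (-2.12) and the collagen cross-linking enzyme gene *Lox* (-3.01, from 2.56 to 0.314 CPM) fell. *Amotl2* (0.29) rose, though its groups overlapped. NF-kB and inflammatory genes were mixed, with 8 higher and 7 lower of 21 (camera adjusted p = 0.63; median 0.12, mean -0.07): *Icam1* (1.21) and *Relb* (1.12) rose and the chemokine gene *Ccl7* (-1.96) fell. Immediate-early and MAPK feedback genes had 9 higher and 12 lower of 25 (camera adjusted p = 0.50), with *Jun* falling from 878 to 356 CPM (-1.30). Interferon-stimulated genes had 13 higher and 9 lower of 27 (camera adjusted p = 0.37), with *Rsad2* (1.07) higher and *Mx2* (-1.45) lower. Of 6 genes in the metallothionein and zinc list 2 rose and 3 fell (camera adjusted p = 0.97), *Mt3* from 11.6 to 2.69 CPM (-2.09). Ribosome biogenesis genes had 9 higher and 12 lower of 28 (camera adjusted p = 0.88), with *Utp20* (-1.30) lower and *Pes1* (1.04) higher.

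**Figure D2:**
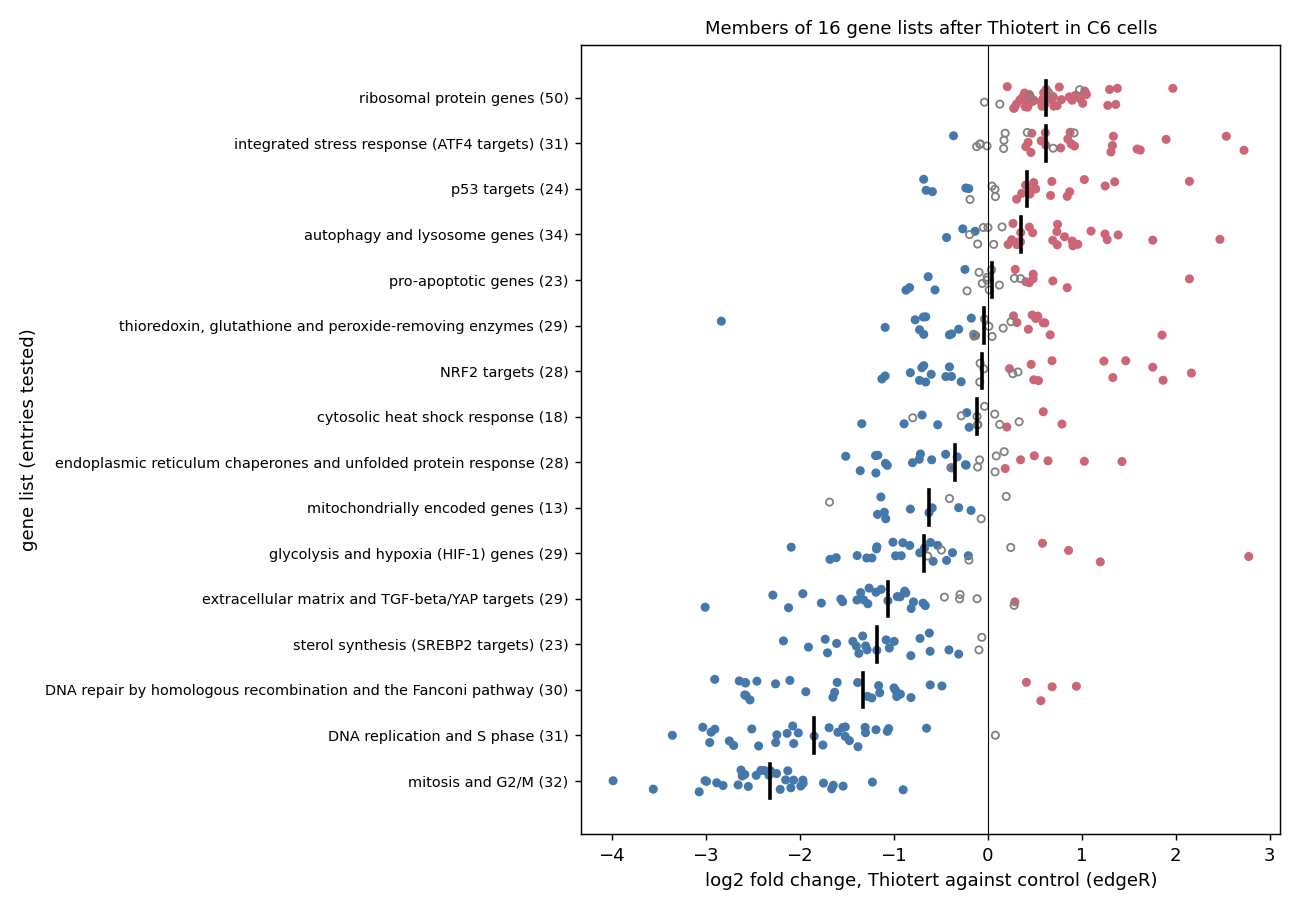
Log2 fold change of each tested entry of 16 gene lists, Thiotert against control (edgeR), with filled red points for entries called higher, filled blue points for entries called lower, open grey points for entries not called, and a black bar at the list median. The medians run from -2.32 for mitosis and G2/M to 0.62 for ribosomal protein genes; points were shifted at random along the vertical axis to separate them.

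Across genes with a symbol, a level of at least 3 on edgeR's log2 CPM scale and non-overlapping groups, the 5 largest falls were in *Top2a* (-3.99), the kinetochore gene *Kntc1* (-3.76), *Iqgap3* (-3.57), *Anln* (-3.56) and the condensin gene *Ncaph* (-3.44). The 5 largest rises were *5_8S_rRNA* (7.12) and *AABR07000398.1* (4.36), *Mcoln3* (2.95), which encodes a lysosomal cation channel, *Ptgds* (2.92), which encodes a prostaglandin D synthase, and *Trib3*. The first 2 lie on 1 contig, JACYVU010000738.1, at 66770 to 66922 and 68076 to 73179, among overlapping ribosomal RNA rows. Reads there cannot be told apart without strand, so these 2 rises are uncertain. Of the rows without a symbol on this contig, ENSRNOG00000065867 (4.76) and ENSRNOG00000063733 (4.66), singled out after their values were seen, rose too and are uncertain in the same way. Such rises were not confined to this contig. Elsewhere, the 1 tested row typed misc_RNA (7.77) and the 1 typed ribozyme (5.28) were called higher, also singled out after their values were seen. Small nucleolar RNA rows were mixed, with 11 of 53 higher and 5 lower, and of 8 microRNA rows none rose and 3 fell. Whether library preparation contributed to these rises was not tested.

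Of 18 glial lineage markers 4 rose and 7 fell (camera adjusted p = 0.65); *Vim* stood at 8755 CPM in control and 7970 CPM in treated cells, a difference that did not pass (edgeR adjusted p = 0.12) except without the low-count filter and under the length correction, and *Nes* fell from 761 to 521 CPM. Neuronal markers had 2 higher and 2 lower of 7 (camera adjusted p = 0.82), with *Map2* falling from 75.0 to 31.3 CPM. Of 5 endothelial markers 1 rose and 2 fell (camera adjusted p = 0.37), *Flt1* from 153 to 45.4 CPM. Of 8 fibroblast and mesenchymal markers, 4 of which are in another list, none rose and 6 fell (camera adjusted p = 0.089), *Prrx1* from 264 to 180 CPM. Of 4 macrophage and microglia markers, too few for a list test, 1 rose and 1 fell: *Fcer1g* rose from 0.296 to 3.85 CPM, and *Cd68*, at 1.08 and 1.86 CPM, did not pass (edgeR adjusted p = 0.089).

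Lists that bear on RNA and library quality also moved. Ribosomal protein entries rose in 45 of 50 cases and none fell, with a median log2 change of 0.62 (camera adjusted p = 1.3e-11, but adjusted p = 0.29 with an estimated correlation), and 16 of the entries share a symbol with another row. *Rplp0* rose from 2359 to 3206 CPM. Their share of all counts was 2.16% ± 0.053 in control and 3.81% ± 0.191 in treated libraries, the latter highest in Thiotert replicate 2 (4.03%), and a correction for gene length and genomic span lowered the list median to 0.37. The 13 listed protein-coding genes of the mitochondrial genome fell in 9 cases and none rose, with a median of -0.63 (camera adjusted p = 7.1e-04, but adjusted p = 0.51 with an estimated correlation). Their most abundant member *Mt-co1* had a log2 change of -0.18 that became 0.06 with library totals alone, and the share of counts on the whole mitochondrial chromosome was 4.73% ± 0.20 and 4.10% ± 0.457 (exact permutation p = 0.2, two-sided; the smallest this design allows is 0.1). Outside that list, 1 of 2 mitochondrial ribosomal RNA rows rose, *AY172581.24* from 581 to 2755 CPM (named after its values were seen), the other, *AY172581.9*, did not pass, at 177 and 162 CPM in Thiotert replicates 1 and 3, 2738 CPM in replicate 2 and 570 CPM in control, and of 12 mitochondrial transfer RNA rows 1 rose and 5 fell by the same edgeR test. Of 8 histone entries, 3 of which share a symbol, 1 rose and 4 fell (camera adjusted p = 0.37); the median of -0.50 became 0.29 without those 3, so no direction is given. *H1f2* (-2.03) and *H1f0* (-0.89) fell, and the latter encodes a linker histone that does not depend on replication. Rows typed as ribosomal RNA, mitochondrial ones included, took 0.248% ± 0.027 of control counts and 0.890% ± 0.826 of treated counts, with 1.84% in Thiotert replicate 2 and 0.415% and 0.410% in replicates 1 and 3.

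Of the 29 lists tested, camera with its preset correlation of 0.01 called 12, and 6 of these held with an estimated correlation: mitosis, S phase, recombination, sterol synthesis, glycolysis and ATF4 targets. Adjusted over the list alone, the counts of higher and lower genes were those given above, except that the thioredoxin and glutathione list had 11 higher and the pro-apoptotic list 7 higher.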

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

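The tests of library composition and depth and the later tests of genomic DNA were chosen after the result was seen; the first test of genomic DNA and that of a few dominant rows were set before. Genes that fell below the low-count filter, which the comparisons leave out, took up 721 CPM in control and 1300 CPM in Thiotert libraries, here scaled to raw library totals without TMM, a ratio of 1.805, and this signal above the control level in unused data called for a closer look. Of these 17586 genes, 5009 had more counts in the treated libraries and 2064 fewer, and the 10 genes with the largest excess held 2.83% of it (2.46% to 6.36% in the single treated libraries). Depth does not account for the ratio, since mean totals differed by a ratio of 1.01, and a shift in composition accounts for part of it, since the ratio was 1.53 after TMM scaling (1.46 for the lowest treated against the highest control library). Genomic DNA was tested 3 times, each time on olfactory and vomeronasal receptor genes, taken as silent in glia. The first test, on all receptor rows, gave a ratio of 1.13 (95% interval 1.09 to 1.18), below the bound it had set for genomic DNA, but 6 rows above the filter held most of its 4980 control counts and so were not silent, which makes that bound unfit; restricted afterwards to the 1254 rows below the filter, the ratio was 2.13 (95% interval 1.76 to 2.60, from 153 and 329 counts), which excludes nothing. The third test compared excess per kb, which DNA would spread evenly, and found 0.058 of that in the other rows below the filter (0.043 to 0.072), which argues against genomic DNA as the main source, though reads lost between similar receptor genes could lower that value. A broad gain of low-level transcripts with Thiotert stays open as a hypothesis that was not tested on its own.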

How the results depend on the processing

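The length correction and the removal of entries with shared symbols were chosen after seeing the data. Over 2009 recomputed values of 112 named-gene entries, 1969 kept direction and side of the threshold, 34 lost the call, 5 gained one and 1 reversed; the reversal was *Mt-co1*, from -0.18 to 0.059 with library totals alone, a scaling that shifts all genes up by 0.24. Calls were lost most often for *Manf*, *Mt-co1*, *Cox6c* and *Mt2A*, and the cause was not tested. The count of changed genes was 8930 with DESeq2 (4006 adjusted p-values not given by the tool) and 9352 with limma-voom, and lay between 8774 and 9566 when single libraries were left out; higher genes then numbered 4318 to 4805, lower genes 4438 to 4761, genes changed 2-fold 2887 to 3003, and list calls were 12 each time. Genes changed at least 2-fold fell to 1564 with limma on log2(FPKM + 1), since that pseudocount shrinks the changes of low genes; with log2(FPKM + 0.1) there were 2659. With estimated correlations 6 lists were called, and fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, called 23. The length correction left 9108 genes called, with 322 of the main calls of the other sign, and library totals alone gave 265 of the other sign. Replicates with the same number did not deviate together (correlations of -0.00044, -0.023 and -0.00085), so no pairing by number was seen. Whether equal numbers mark a shared day or culture cannot be told from this. With the replicate block 9308 genes were called, against 9373 without it, and no call of a list or named gene changed. *Manf* lay near 1 CPM, where counts are few; whether depth ended its calls was not tested. Of 10 splits of the 6 libraries into 3 and 3, too few for a share below 0.05, the real one (1 of the 10) gave the 9373 changed, 4730 higher, 4643 lower and 2859 2-fold genes, and the highest of the others was 0 by edgeR (87 genes at an unadjusted p of 0.05, and 0 by limma-voom). Every other split mixes treated and control libraries in both of its groups, so the treatment effect enters the spread. Their low gene counts were therefore to be foreseen and are no reference for the real counts. For the list tests 3 of the 10 splits gave as many calls as the real 12, and the highest of the others was 12, so the number of list calls does not set the real split apart; every other split still leaves 2 libraries of a group against 1.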

Other observations

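The 14 gene families tested here were picked after seeing the data, as were their tests. Their members were matched by gene symbol and not checked further, so a family may hold genes that do not belong to it. The V-ATPase match included *Atp6v1fnb* (log2 change 2.16), and the initiation factor match included the kinase gene *Eif2ak4* (-1.66). Camera called 8 of the families, and none of the 14 held with an estimated correlation (adjusted p = 0.068 or above). The 6 not called were Rab GTPases, ephrin receptors and chaperonin subunits (camera adjusted p = 0.069 each), Sm and LSm proteins (0.39), cadherins (0.77) and translation initiation factors (0.92). The length correction brought chaperonin subunits, 5 of 7 of them lower, past the threshold (camera adjusted p = 0.012; median -0.29 before and -0.35 after). In the called families that fell, the median fall was larger than the shift of 0.24 between scalings. Genes matched as subunits of the V-ATPase, the pump that acidifies lysosomes, rose in 11 of 16 cases and fell in 1. Their median log2 change was 0.57 (camera adjusted p = 4.4e-04, but adjusted p = 0.068 with an estimated correlation). Integrins, the receptors that bind cells to the matrix, fell in 12 of 17 cases and rose in 2 (median -1.06; camera adjusted p = 4.4e-04; adjusted p = 0.23 with an estimated correlation), with *Itga3* falling from 897 to 215 CPM and *Itga6* from 714 to 171 CPM. Nucleoporins fell in 17 of 21 cases and rose in 2 (median -0.65; camera adjusted p = 1.9e-04; adjusted p = 0.068 with an estimated correlation), *Nup205* from 201 to 38.7 CPM. Centromere proteins fell in 17 of 19 cases and none rose (median -1.88, camera adjusted p = 1.4e-06, but adjusted p = 0.089 with an estimated correlation). Kinesins, which include mitotic motors, fell in 22 of 34 and rose in 5 (median -0.82, camera adjusted p = 1.9e-04, but adjusted p = 0.068 with an estimated correlation). The mitosis list also holds centromere protein and kinesin genes, such as *Cenpe* and *Kif11*, so these falls may in part repeat the fall of that list. Mitochondrial ribosomal proteins rose in 43 of 71 cases and fell in 7 (camera adjusted p = 8.3e-04; adjusted p = 0.48 with an estimated correlation), and the length correction lowered their median from 0.32 to 0.11 and ended the call (camera adjusted p = 0.30). Cytosolic aminoacyl-tRNA synthetases rose in 10 of 14 cases and fell in 3 (camera adjusted p = 0.032; adjusted p = 0.31 with an estimated correlation), and laminins fell in 7 of 8 and rose in 1 (camera adjusted p = 0.013; adjusted p = 0.48 with an estimated correlation); with the length correction both calls were lost, at a synthetase median that hardly moved (0.30 before and after; camera adjusted p = 0.051) and a laminin median that went from -0.73 to -0.49 (camera adjusted p = 0.077). The ATF4 list also names synthetase genes, such as *Sars1*, and the autophagy and lysosome list names the V-ATPase genes *Atp6v0d1* and *Atp6v1h*. The rises of these 2 families may therefore in part repeat the rises of those lists. One further row on the contig of *5_8S_rRNA*, a ribosomal RNA row, held 159162 counts in Thiotert replicate 2, against 2751 and 2472 in the other treated libraries and 14946 to 20605 in controls. The number of genes with at least 1 count was 16663 ± 117 in control and 18100 ± 172 in treated libraries (exact permutation p = 0.1, the smallest possible).

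The tests in this and the next paragraph were fixed before their results were seen, except those of span slopes, of scaling and without the entries that share a symbol. The plain correlations and those outside the gene lists had no prediction fixed in advance, and the length correction itself was an added setting. Genes with a long genomic span were lower with Thiotert relative to genes with a short one. In the fifth of the 13084 genes with the shortest span (median 3029 bases) the median log2 change was 0.31, and in the fifth with the longest (median 113554 bases) it was -0.37. Across genes, which are not independent replicates, the partial Spearman correlation with span, given transcript length and level, was -0.203 (95% bootstrap interval -0.219 to -0.186). With transcript length, given span and level, it was -0.013 (-0.030 to 0.003). The plain Spearman correlations were -0.299 with span and -0.219 with length. Transcript length here is the deposited gene length, which may differ from that of the transcripts present, and error in it would weaken its partial correlation. The value for length argues against loss of long transcripts through RNA fragmentation only as far as the deposited length holds. Outside the gene lists (12435 genes) the partial correlations with span and length were -0.205 and -0.0057. The group gap in the span slopes of the libraries was 6.53 times the widest range within a group (2.70 times for transcript-length slopes), so the trend does not rest on 1 library, but a bias shared by all 3 treated libraries would give the same and stays open. Lower output of long genes, through transcription or RNA stability, may account for the trend as a hypothesis that these counts cannot take further.

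The rise of ribosomal protein genes (median log2 change 0.62) was set against the same trend, since these genes are short. After correction for transcript length and span the median was 0.37 (95% bootstrap interval 0.30 to 0.46). The trend as fitted may thus explain part of the rise, and a rise was left after correction. The bootstraps in this paragraph drew genes, and the entries of this list are not independent (estimated correlation 0.32). Their intervals therefore do not measure the spread between libraries, and do not settle whether the trend explains all of the rise. The list median lay 0.59 (95% bootstrap interval 0.50 to 0.72) above the median of all genes tested, but a scaling moves both alike, so this value tests nothing about the choice of scaling. The share of counts in these genes was above every control in all 3 treated libraries. Without the 16 of 50 entries that share a symbol with another row the median was 0.62 (camera adjusted p = 1.1e-10; for the whole list adjusted p = 0.29 with an estimated correlation), but reads shared with copies under other names stay open, as does a change in total RNA per cell, which counts alone do not show.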
